A study of Homo sapiens with 4 samples.

How the data were processed

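Small RNA libraries of total RNA from small extracellular vesicles of HT29, an established human colon cancer cell line, were analysed. The 4 libraries formed 2 groups of 2, from cells with a non-targeting shRNA (the control) and from cells with an shRNA against p53. Per the labels' protocols, vesicle RNA was isolated with a column kit, the cDNA was size-selected to 18 to 40 nt, and cells were at passages 5 to 15.

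The authors deposited a table of counts, whole numbers of reads per annotated RNA that are not normalized, with an annotation of RNAcentral identifiers. Per the submitters' processing notes, bcl2fastq 2.19, BWA 0.7.17, Subread 1.6.3 and the GRCh38 build were used. The table held 155642 features on chromosomes 1 to 22. The annotation held 161443 identifiers, of which 5801 had no row of counts, and these included all 22 of type tRNA. No count column belonged to another sample.

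How reads were assigned to features is not given in the sources used here and was examined in the deposited counts. Of 66527 features with no base outside other features, strand ignored, 0 had a count in any library, against 46090 of the 89115 features with such bases (51.7%). Of 3257 features whose own bases appear only when strand is used, 0 had a count. This is the pattern of a count that leaves out reads overlapping more than 1 feature and does not use strand. All 2459 mature miRNA features lie within other features and had a count of 0 in all 4 libraries, so no level of a mature miRNA is reported. Of 2234 hairpin features, 1499 had bases of their own, and counts on hairpins came from these alone. Sense and antisense reads cannot be told apart. Near-identical copies can share reads, so single copies of 5S, 5.8S, 18S, U1, U2, Y RNA and tRNA genes are uncertain.

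Types in the annotation were grouped into RNA classes written down before the data were examined. Features were named by GENCODE 29 genes whose exons covered at least 50% of their length (99592 features), with bedtools 2.31.1, and features on ribosomal or tRNA genes were found by overlap with RefSeq genes of the same build. Features with several loci (18S, 5.8S, 5S, U1 and U2) were named by the genes at their loci. Y RNA features were placed with RNY1, RNY3 or RNY4 by the smallest edit distance between transcript sequences, and RNY5 was not among these 3 references. The families and the tRNA gene group were defined after the data were examined.

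The main test was edgeR 4.0.16's quasi-likelihood test on the counts as deposited, with TMM normalization, edgeR's filter on low counts (2780 features tested) and Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. Normalized values are CPM, counts scaled to a common library size, with TMM factors of 0.637 and 1.12 for control replicates 1 and 2 and of 1.13 and 1.25 for the p53 shRNA replicates. The SE of a log2 change is that of the difference between group means of log2 CPM (prior count 2). RNA classes and 12 miRNA lists, both fixed before the data were examined, were tested with camera of limma 3.58.1, at a preset correlation of 0.01 and with an estimated one, where 3 or more members were tested. Shares of counts were compared by two-sided exact permutation tests, which cannot give a p below 0.333 with 2 libraries against 2. Intervals of shares are 95% Wilson intervals. They and the floor of 3 counts, taken over a group, cover counting error only.

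The features named follow a rule set before the data were examined. It takes up to 10 hairpins and 5 other features per direction that pass the adjusted threshold, have at least 10 CPM in the higher group and separate the groups, then the 10 most abundant hairpins and up to 4 members of each list. As 0 features passed, up to 5 places per direction went to those with the smallest unadjusted p that met the other conditions. Only features with a gene name by position could take a place, so unnamed features with a smaller p were passed over. RNY1, RNY3, the vault RNAs, the ribosomal RNAs, the feature beside RNA5-8SP5, U1, U2, RNU5A-1 and the tRNA gene features were chosen after their values were seen. The knockdown itself was not analysed here.

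The test was run on simulated counts with the real means, library sizes and 2780 features, 200 of them changed, in 5 runs. At a low dispersion of 0.01 it recovered 97.4% of 4-fold and 100% of 16-fold changes, with 4.19% false calls. At the dispersions fitted to these libraries it recovered 0% of 4-fold and 0.563% of 16-fold changes. Alternatives were DESeq2 1.42.0 size factors, library totals, the DESeq2 Wald test, limma voom, other filters, the replicate number as a block, each library left out, collapsed features, a fit of hairpins alone and, added after the data were examined, a fit without ribosomal features and the hairpin share without the feature over RNA5SP387.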

Results

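Small RNA of 18 to 40 nt was sequenced from small extracellular vesicles, the membrane-bound particles that cells release, of HT29 colon cancer cells. Counts on annotated RNAs longer than 40 nt are thus of fragments, and the level of a fragment need not be that of the whole RNA. The libraries were 2 from cells with a non-targeting shRNA, called control here, and 2 from cells with an shRNA against p53, a tumour suppressor and transcription factor. Counts totalled 1099694 and 938754 in control replicates 1 and 2, and 2611032 and 1940942 in p53 shRNA replicates 1 and 2. The number of features with a count was 19931 and 18575 in the controls and 34078 and 28314 in the p53 shRNA libraries, but 18433, 18575, 22116 and 20348 at the depth of the shallowest library. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

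Ribosomal RNA genes held most counts of the vesicle libraries, 69.0% ± 1.07 (SD, n = 2) in the controls and 68.6% ± 0.946 (SD, n = 2) with p53 shRNA. The positions of 18S held 48.2% ± 0.416 and 47.5% ± 14.9, and those of 5.8S 12.4% ± 0.907 in the controls against 6.27% ± 1.24 with p53 shRNA. The share at 5S was 8.32% ± 2.38 in the controls, while the p53 shRNA libraries held 25.0% in replicate 1 and 4.26% in replicate 2. Features over tRNA genes held 0.824% ± 0.0388 of control counts and 0.175% ± 0.0506 of p53 shRNA counts, 4.70 times less. Vault RNAs, small RNAs of the vault particle, held 1.07% ± 0.341 against 0.331% ± 0.264, and snRNAs of the spliceosome 5.66% ± 1.96 against 3.51% ± 0.711. The vault RNA difference lay in VTRNA1-2, with 0.975% ± 0.250 against 0.181% ± 0.129. VTRNA1-3 held 0.0955% ± 0.0903 against 0.149% ± 0.135, with overlapping groups, and VTRNA1-1 had 0 counts in every library. The groups did not overlap for 5.8S, tRNA genes, vault RNA and snRNA, all lower with p53 shRNA. Higher with p53 shRNA, also without overlap, were rRNA features other than 5S and 5.8S (0.107% ± 0.0129 against 0.246% ± 0.0621) and the snRNA RNU5A-1 (0.00502% ± 0.00152 against 0.0140% ± 0.00138). In all, 14 of the 31 shares did not overlap, and 41.5% of the 2780 features tested, where chance alone gives 33.3%. Some shares contain others. Each share without overlap gave p = 0.333 in the two-sided exact permutation test, the smallest that 2 against 2 allows, and an adjusted p of 0.738 over the 31 shares compared. The 95% Wilson interval of any single share was at most 0.101 percentage points either way.

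The 18S counts came from features typed as long non-coding RNA that lie on the opposite strand of 18S. The larger one has 3 loci of 923 bases between 8210384 and 8438551 on chromosome 21 (GRCh38), within RNA18SN1, RNA18SN2 and RNA18SN3. Counts per locus of this feature and of a feature with 1 locus at 8254592 to 8255514 had ratios between 0.995 and 1.0 in the 4 libraries. Outside ribosomal genes, long non-coding RNA features held 20.5% ± 4.46 of control and 24.6% ± 4.23 of p53 shRNA counts. Of these, a single feature beside the 5.8S pseudogene RNA5-8SP5 (chromosome 2, 132254554 to 132280556) held 6.71% ± 0.594 and 6.96% ± 2.59 of all counts, and its counts were 13.1% to 15.2% of those at 18S in the 4 libraries. snoRNAs, which guide RNA modification, held 2.31% ± 1.23 and 1.75% ± 1.10, and Y RNAs 1.38% ± 0.115 and 1.10% ± 1.21, so that these differences were smaller than the spread within a group.

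**Figure D1:**
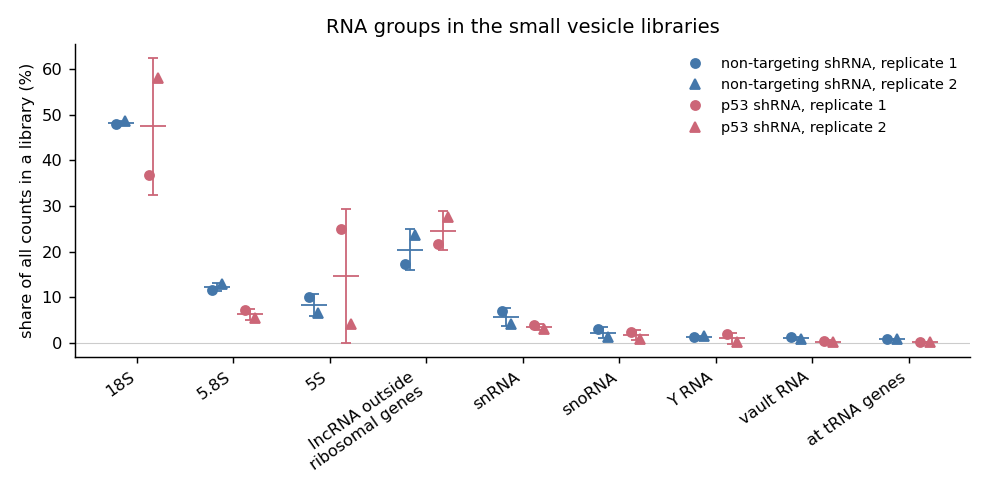
Share of all counts in each library (y axis, %) for 9 RNA groups (x axis), with 1 point per library, the group mean as a line and the SD as bars (n = 2). The 5.8S and tRNA gene shares of both p53 shRNA libraries lie below those of both controls, and the 5S share of p53 shRNA replicate 1 stands apart at 25.0%.

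The groups ask whether an shRNA against p53 in HT29 cells alters the small RNA of their vesicles. RNY1, a Y RNA bound by the Ro60 protein, had 11501 ± 12.7 CPM in the controls and 443 ± 133 CPM with p53 shRNA (SD, n = 2), a log2 change of −4.70 (SE 0.31). Before TMM scaling its share of all counts was 0.710% and 1.24% in the controls and 0.0374% and 0.0645% with p53 shRNA, so the controls agreed less closely than in CPM. RNY3 had 154 ± 51.9 and 16.5 ± 7.53 CPM (log2 change −3.21, SE 0.57), and the vault RNA VTRNA1-2 13053 ± 7966 and 1647 ± 1267 CPM (−2.99, SE 1.10). The change of RNY3 was −3.64 without p53 shRNA replicate 1 and −2.54 without replicate 2, and that of VTRNA1-2 was −3.96 without p53 shRNA replicate 1 and −2.06 without replicate 2. In all 3, both p53 shRNA libraries lay below both controls, but their adjusted p in edgeR's quasi-likelihood test was 0.122, 0.257 and 0.261. VTRNA1-3, another vault RNA, had 1440 ± 1620 and 1362 ± 1293 CPM, with no separation of the groups and a log2 change from −1.49 to 2.03 when a library was left out. Across all features, 0 of 2780 passed an adjusted p of 0.05, and the smallest adjusted p was 0.122. At an unadjusted p under 0.05, 121 features were higher and 217 lower with p53 shRNA, 338 in all where chance alone gives 139. On library totals the balance turned, with 308 higher and 170 lower, and with no filter on low counts 2027 of 46090 features were higher and 677 lower. Without a filter the median log2 change of all features was 1.38. Both p53 shRNA libraries were deeper than both controls, and the part of depth in this balance was not tested. At a mean CPM of at least 10 the balance was near even, with 93 higher and 94 lower. It kept its direction with DESeq2 size factors (146 higher, 223 lower) and limma voom (79 and 222). The excess over chance and the balance both depended on which library was left out. The DESeq2 Wald test called 37 features (1 higher, 36 lower) and limma voom 0. With the spread of these libraries (biological coefficient of variation 0.672), simulated 16-fold changes were recovered in 0.563% of cases, so that the count of 0 does not exclude large differences.

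RNY1 lies at 148987136 to 148987248 and RNY3 at 148983755 to 148983856 on chromosome 7, and VTRNA1-2 at 140718925 to 140719013 and VTRNA1-3 at 140726158 to 140726246 on chromosome 5. RNY1 counts were 7803 and 11602 in the controls and 977 and 1251 with p53 shRNA. The DESeq2 Wald test gave RNY1 an adjusted p of 0.00103. In edgeR's fit without p53 shRNA replicate 1 its log2 change was −4.32. With no filter on low counts the change was −3.90 for RNY1, −2.36 for RNY3 and −2.07 for VTRNA1-2.

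**Figure D2:**
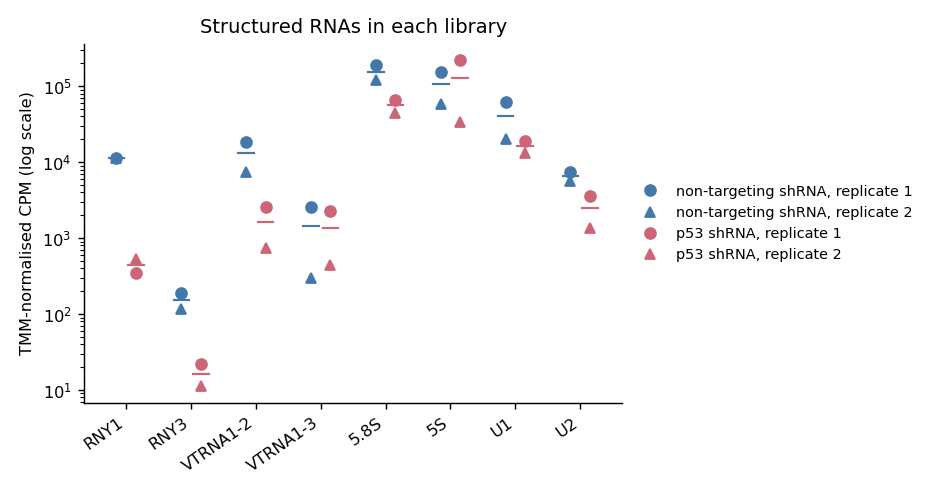
TMM-normalised CPM (y axis, log scale) of 8 structured RNAs (x axis) in each library, with 1 point per library and the group mean as a line. RNY1 lies near 11501 CPM in both controls and near 443 CPM with p53 shRNA, while VTRNA1-3 and 5S differ more between replicates than between groups.

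Y RNA features as a class were lower with p53 shRNA than the other features (camera, adjusted p = 8.77e-10, 61 features, median log2 change −2.30, mean −1.28). With an estimated correlation the call was lost (adjusted p = 0.677 with an estimated correlation). Of the 61, 30 were lower and 0 higher at an unadjusted p under 0.05, 27 were lower when adjusted over the list alone, and 0 when adjusted over all features in the main edgeR fit. The DESeq2 Wald test called 3 copies of RNY1 or RNY3 over all features. The class was not uniform. The 31 copies of RNY1 had a median log2 change of −3.01, and 25 of them were lower at an unadjusted p under 0.05. The 4 copies of RNY3 had a median of −3.03. The 26 copies of RNY4 had a median of 1.19, which depended on the libraries used: it was −1.53 and 2.45 without p53 shRNA replicates 1 and 2, and 3.74 and 0.36 without control replicates 1 and 2. Counts of all 62 RNY4 copies in the table summed to 5328 and 775 in the controls and to 49136 and 2849 with p53 shRNA. The RNY4 gene itself had 11 and 1 counts in the controls and 127 and 12 with p53 shRNA, so nearly all of these lay on other copies. The tested RNY4 copies had a median identity of 85.4% to RNY4, so the family is not a measure of RNY4 itself. The same limit holds for the other 2 families, with median identities of 86.7% to RNY1 and 90.7% to RNY3. The medians of RNY1 and RNY3 copies stayed between −3.53 and −2.48 when any library was left out. Copies can share reads, so their number is not a number of independent RNAs.

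snoRNAs (117 features, median log2 change −0.93) and snRNAs (18 features, −1.20) were also lower than the other features by camera (adjusted p = 5.16e-07 and 0.0108), and lncRNA features were higher (2557 features, median 0.10, adjusted p = 1.0e-09). None of these calls held with an estimated correlation (adjusted p = 0.677 with an estimated correlation for snoRNAs and snRNAs, and 0.118 for lncRNAs). The lncRNA features were most of the 2780 tested, and at an unadjusted p under 0.05 more of them were lower (181) than higher (120). Among snRNAs, U1 had 40988 ± 29792 CPM in the controls and 16248 ± 4165 with p53 shRNA, and U2 had 6614 ± 1288 and 2493 ± 1608 (edgeR adjusted p = 0.599 and 0.637). The log2 change of U1 went from −1.33 to −0.45 without control replicate 1, and that of U2 from −1.41 to −2.16 and −0.61 without p53 shRNA replicates 1 and 2. The vault RNA (3 features), ribosomal RNA (8) and miRNA hairpin (13) classes were not called (camera adjusted p = 0.226, 0.598 and 0.702). Scaling by library totals raised the median of all features from 0.05 to 0.49 on the log2 scale and the vault RNA median from −0.43 to 0.10. The medians of snoRNAs (−0.31), snRNAs (−0.45) and Y RNAs (−1.62) stayed below 0 with that scaling. Without control replicate 1, Y RNA was the 1 class called (median −1.23, camera adjusted p = 0.000394, and adjusted p = 0.892 with an estimated correlation), and the snoRNA median was 0.23. Without p53 shRNA replicate 2 snoRNAs and snRNAs were not called (camera adjusted p = 0.180 and 0.527), nor were they without a filter on low counts (0.257 and 0.838).

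**Figure D3:**
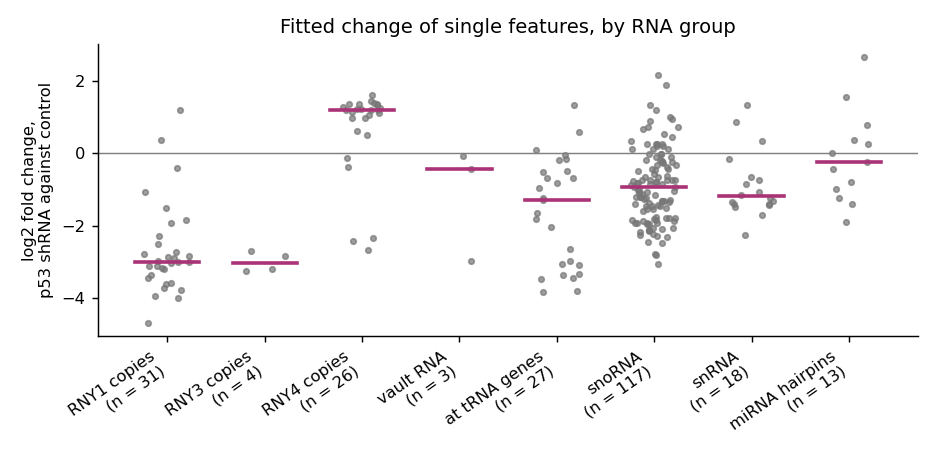
Fitted log2 fold change of p53 shRNA against control (y axis) for single tested features of 8 RNA groups (x axis), with 1 point per feature and the median as a line. RNY1 copies centre on −3.01, RNY3 copies on −3.03 and RNY4 copies on 1.19, the last of which turned to −1.53 without p53 shRNA replicate 1.

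miRNA was measured only through reads on hairpins outside mature miRNAs, as mature miRNAs were at 0 in every library. Hairpins held 0.0653% ± 0.0153 of control counts and 0.0559% ± 0.000818 of p53 shRNA counts (SD, n = 2), and the groups overlapped (two-sided exact permutation p = 1.0). The direction rested on 1 feature, over the 5S pseudogene RNA5SP387, which had 256 and 406 counts in the controls and 345 and 201 with p53 shRNA. Without it, a comparison chosen after the data were seen, hairpins held 0.0320% ± 0.00114 of control and 0.0441% ± 0.00120 of p53 shRNA counts, and the groups did not overlap (two-sided exact permutation p = 0.333, adjusted p = 0.738). Of 13 hairpins tested, 0 passed in edgeR's test and 0 had an unadjusted p under 0.05, and DESeq2 and voom also called 0. MIR431 (chromosome 14, 100881007 to 100881120) had 9.62 ± 0.998 CPM in the controls and 28.5 ± 6.98 CPM with p53 shRNA, and MIR103A2 7.65 ± 0.388 and 13.3 ± 3.08 CPM. Lower values with p53 shRNA were found for MIR26A1 (19.7 ± 2.89 and 8.29 ± 4.45 CPM), MIR2110 (29.8 ± 18.3 and 11.1 ± 0.0522 CPM) and MIR671 (129 ± 42.6 and 65.4 ± 38.5 CPM). The feature over RNA5SP387, the most abundant hairpin feature, lies on chromosome 14 (75604209 to 75604261) and had 390 ± 17.3 and 105 ± 26.2 CPM. None of these passed (edgeR adjusted p between 0.552 and 0.777). Of the other abundant hairpins, MIR3648-2 had 24.9 ± 21.2 and 18.2 ± 13.6 CPM, MIR7-1 14.8 ± 0.0757 and 17.8 ± 13.6, MIR191 11.6 ± 10.8 and 14.6 ± 5.46, and MIR7641-1 9.15 ± 6.68 and 8.04 ± 0.759, and the log2 change of each turned its sign when some library was left out. MIR3648-2 starts at 8208473 on chromosome 21, close to the 18S gene RNA18SN2 (8209631 to 8211499). When 14 hairpins alone were filtered, normalized and adjusted together, MIR431 was called higher (log2 change 2.57, adjusted p = 0.00356). Its change was 1.56 in the main fit and between 1.53 and 1.90 when a library was left out. In the fit of 14 hairpins alone the log2 change was −0.02 for MIR26A1, −0.08 for MIR671, −0.31 for MIR2110 and −0.73 for the feature over RNA5SP387, against −1.24, −0.98, −1.41 and −1.90 in the main fit, and 1.79 for MIR103A2 against 0.78. With a library left out, the change ran from −1.83 to −0.57 for MIR26A1, from −1.49 to −0.35 for MIR671 and from −1.81 to −0.74 for MIR2110.

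None of the 12 miRNA lists had the 3 tested hairpins that a set test needs, and 0 hairpins of any list were called. Hairpins with any count numbered 4 in the list of colon oncomiRs, 3 each in the intestinal epithelial, miR-17-92 and miR-200 lists, 2 in the p53-responsive list, and 1 each in the mutant p53, fibroblast activation, stromal and blood lists. The let-7, muscle and neural, and vesicle-sorted lists had 0. MIR7-1, of the intestinal epithelial list, was the 1 list member tested. The 31 hairpins of the p53-responsive list, miRNAs described as induced or matured by p53, held 21 counts in all 4 libraries together.

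Other features separated the groups at low counts, all at an adjusted p of at least 0.122 in the main edgeR fit. The DESeq2 Wald test called ATG9B, SLC6A13, RNF130, LRRC34P1, AC016590.1 and CTC-338M12.4 (adjusted p between 0.0112 and 0.0497). They lie in exons of the genes named, and reads of either strand were counted. The feature in ATG9B, an autophagy membrane protein (chromosome 7, 151019837 to 151024499), had 16 and 20 counts in the controls and 1 and 2 with p53 shRNA, a ratio of 36.5 with a counting interval of 11.5 to 185, and its log2 change of −5.03 was −4.41 without p53 shRNA replicate 1. SLC6A13, a GABA transporter (chromosome 12, 237150 to 238309), had 19 and 13 against 2 and 1 counts, and RNF130, a RING finger protein (chromosome 5, 179918911 to 179920229), 18 and 13 against 2 and 1. LRRC34P1 had 27.4 ± 9.28 against 0.822 ± 0.657 CPM (log2 change −4.97, but −4.18 and −5.71 without p53 shRNA replicates 1 and 2) and AC016590.1 36.2 ± 13.4 against 1.0 ± 0.404 CPM. In the other direction, CTC-338M12.4 had 0 counts in both controls and 33 and 51 with p53 shRNA, at least 9.21-fold higher against a floor of 3 counts over the group. Its fitted log2 change of 7.85 was 7.24 without p53 shRNA replicate 2. LINC00602 also had 0 in both controls and 55 and 13 with p53 shRNA, at least 7.45-fold higher. That bound rests mostly on p53 shRNA replicate 1, with 19.6 CPM against 5.57 in replicate 2. SPRY1, an inhibitor of receptor tyrosine kinase signalling (chromosome 4, 123396811 to 123398337), had 1 and 0 against 149 and 18 counts, a ratio of 54.9 with a counting interval of 9.72 to 2182. Its fitted log2 change of 5.46 was 3.55 without p53 shRNA replicate 1, 4.38 without control replicate 2, 6.47 without p53 shRNA replicate 2 and 8.91 without control replicate 1. RPSAP57 had 1 and 0 against 35 and 29 counts, a ratio of 21.0 with an interval of 3.64 to 844, and its log2 change of 4.20 was 3.15 without control replicate 2 and 7.67 without control replicate 1. ADAMTS10, a secreted metalloprotease (chromosome 19, 8589941 to 8593516), had 2.47 ± 0.685 CPM in the controls and 24.5 ± 3.18 CPM with p53 shRNA.

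Replicates differed widely. The Pearson correlation of log2 CPM across features, which are not independent replicates, was 0.651 between the controls and 0.747 between the p53 shRNA libraries, and ranged from 0.517 to 0.695 between libraries of different groups. Of these 4 values between groups, 2 lay above that between the controls. A single feature, the 18S feature with 3 loci, took between 27.7% and 43.5% of the counts of a library.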

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

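Of 374 values of 29 named features under the alternatives, 350 kept their direction, 24 in 7 features changed sign, and none did so past the threshold. The count of 0 changed features and of 0 with a fold of 2 or more was also given by DESeq2 size factors, library totals, limma voom, no filter, a mean CPM of at least 10, collapsed features, each library left out, and a fit without ribosomal features chosen after the data were seen. The DESeq2 Wald test gave 37 for both, with 539 adjusted p not given. With replicate number as a block (replicate block) both counts were 103 (12 higher, 91 lower), of which 36 were shared with the DESeq2 calls, and which included 16 copies of RNY1 or RNY3 and 2 tRNA gene features. The 11 named features among them were RNY1 (adjusted p = 0.000342), VTRNA1-2 (0.00994), 5.8S (0.0273), ATG9B, LRRC34P1, AC016590.1, SLC6A13, RNF130, CTC-338M12.4, SPRY1 and LINC00602 (between 0.00290 and 0.0407). The replicates share only a number, and differences between replicates 1 and 2 correlated at 0.395 between the groups. Libraries of different groups correlated at 0.695 and 0.657 where they shared a number and at 0.603 and 0.517 where they did not. On library totals, 308 features were higher and 170 lower at an unadjusted p under 0.05, against 121 and 217 with TMM. A fit of 14 hairpins alone, which changes the filter, the normalization and the adjustment together, gave 1 changed hairpin instead of 0. Classes called numbered 4, but 2 without a filter on low counts, and 1 to 5 when a library was left out, and 0 held with an estimated correlation in any of these settings. The miRNA lists could be tested only without a filter, where 0 of 4 were called. The hairpin share difference, p53 shRNA minus control, was −0.00935 percentage points of all counts, −0.0201 without control replicate 1, 0.00144 without control replicate 2, 0.0121 without the feature over RNA5SP387 (chosen after the data were seen) and 0.216 percentage points of miRNA, tRNA, Y RNA, snRNA and snoRNA counts. The within-group correlation was 0.699, and 0.649 for a mean CPM of at least 10. For these differences the cause was not tested. Leaving out a library leaves 1 in its group, whose spread is then assumed to be that of the other group. Of 2234 hairpins, 211 had any count, at these depths and with 1499 that had bases of their own.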

Other observations

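The summary over tRNA gene features and the tests of scaling, shared reads, replicate order and counting of overlapping reads were chosen after the results were seen, while the edgeR and DESeq2 values of single features come from planned tests. Features over tRNA genes, a group on which no set test was run, were mostly lower in the p53 shRNA libraries. Of 27 tested, 24 had a fitted log2 change below 0 (median −1.30), 10 were lower at an unadjusted p under 0.05, 0 were called in the main edgeR fit (smallest adjusted p = 0.187) and 3 by the DESeq2 Wald test. The median ran from −2.17 to −0.43 over the alternatives. The feature over TRK-CTT2-1, a lysine tRNA gene on chromosome 1 (146038859 to 146040567), had 1274 and 949 counts in the controls and 334 and 182 with p53 shRNA. Features over the histidine tRNA genes TRH-GTG1-5, TRH-GTG1-7, TRH-GTG1-8 and TRH-GTG1-9 had fitted log2 changes of −3.34, −3.48, −3.37 and −3.46. Their counts were 1093 and 905 against 503 and 158 for TRH-GTG1-5, 864 and 631 against 361 and 96 for TRH-GTG1-7, 833 and 608 against 365 and 109 for TRH-GTG1-8, and 867 and 624 against 336 and 123 for TRH-GTG1-9. The feature over TRG-GCC2-6, a glycine tRNA gene, had 1863 ± 449 CPM in the controls and 217 ± 95.3 CPM with p53 shRNA (SD, n = 2). TRX-CAT1-8 went the other way, with 68.0 ± 45.7 and 171 ± 68.6 CPM. These features are typed as long non-coding RNA, and identifiers of type tRNA had no row of counts. The features over histidine tRNA genes had similar counts within each library. Copies can share reads, so the number of lower tRNA gene features is not a number of independent RNAs. Reads shared between copies were not tested for tRNA genes.

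RNY1 and RNY3 copies were low in the p53 shRNA libraries. Scaling of the libraries is argued against as the whole cause, since the median log2 change of the 35 copies lay between −3.07 and −2.57 over the scaling alternatives. Among these alternatives, limma voom and the replicate block used the TMM scaling of the main fit. All were relative to a library's own counts, so a difference in total RNA was not tested. Reads shared between copies, as the reason for how many copies moved together, cannot be told apart from chance: 32 of 35 copies had another copy of their family at the same counts within counting error, but 100 draws of lncRNA features of similar total gave a median of 29 and up to 32, and only 5 of the copies had at least 100 counts. Of these 5, 2 had such a copy, where the draws gave a median of 0 and up to 2. An effect of p53 shRNA on RNY1 in the vesicles stays open as a hypothesis: its log2 change was −4.70, against at most 0.62 between libraries of a group in TMM-scaled CPM, at an adjusted p of 0.122 in the main edgeR fit and of 0.00103 in the DESeq2 Wald test. In shares of all counts the controls were 19.1 times higher, and replicate 1 was 0.574 times replicate 2 in the controls and 0.581 times with p53 shRNA. RNY1 was chosen after its values were seen. The comparison rests on 2 libraries per group, and the labels do not say whether these came from separate cultures.

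snoRNA features were higher in replicate 1 than in replicate 2 of both groups, in 111 of 117 for the controls (median log2 difference 1.71) and in 86 of 117 for p53 shRNA (0.73). The order was not particular to snoRNAs. It also held for snRNAs (17 and 15 of 18), vault RNAs (3 and 3 of 3) and Y RNAs (48 and 49 of 61). With p53 shRNA the median log2 difference was larger for Y RNAs (0.92) and vault RNAs (1.76). The order did not hold in both groups for lncRNA features (1394 and 1246 of 2557), rRNAs (7 and 4 of 8) or miRNA hairpins (7 and 2 of 13). TMM scaling is argued against as the whole cause, because the snoRNA share of all counts was 2.20 times higher in replicate 1 of the controls (95% counting interval 2.16 to 2.25) and 2.59 times with p53 shRNA (2.55 to 2.63). The TMM factors of the controls, 0.637 and 1.12, raise replicate 1 over replicate 2 in CPM, so scaling is a part of the control difference of 1.71. A preparation shared by libraries of a number is a candidate explanation, with a correlation of 0.395 across features between the replicate differences of the groups. The labels name no batch, so it cannot be told apart from a chance order of the replicates. No biological explanation was tested for this pattern.

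Mature miRNAs were at 0 in every library. Leaving out reads that overlap more than 1 annotated RNA is a candidate explanation, because 0 of 66527 features without a base of their own had a count, against 51.7% of the others. Vesicles without miRNA cannot be excluded from this table, since 0 of the 2459 mature miRNA features had a base of its own to be counted on.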
